A study of Mus musculus with 6 samples.

How the data were processed

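Total RNA from 6 samples, 3 with a hairpin against Jmjd1c and 3 with a control hairpin, was hybridised to 1-colour Agilent mouse arrays with 62976 features. Per the file headers, spots were read with Agilent Feature Extraction 11.0.1.1, and the headers name the mm9 genome build. Per the file headers, the processed signal is an intensity, background-subtracted and not normalized between arrays, and the median and background signals are intensities too. The authors' deposited table holds log2 values, 31672 rows for 29351 probes, and the submitters' processing notes name limma without a version. Each column of that table correlated best with its own array (lowest r = 0.991). Its column medians were 8.86, 8.87, 8.86, 8.86, 8.87 and 8.86. The lowest correlation with values made here by normexp (offset 50) and quantile normalization was 0.99997, across probes, so the direction is not in doubt, while the exact filter on its rows is not given in the sources used here. It was used as an alternative.

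The main values were log2 of the processed signal minus the 75th percentile of each array over the 59305 non-control spots. Spots with an outlier mark, 129 to 248 per array, were left out, and no non-control spot was saturated. Spots of 1 probe were averaged, giving 55681 probes. The 36323 probes well above background on at least 3 of the 6 arrays were tested. The lowest share of spots well above background, 54.4%, and a negative-control signal outside Agilent's stated range were both found on control replicate 1. A probe that was not well above background on any array of a group has only a bound there. It is given as at least N-fold, from the bright group's mean against, per array, the higher of the probe's own signal and the lowest signal among probes well above background. Such a bound holds for the main values only.

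The scanner files give accessions and no gene symbols. Symbols came from a RefSeq table of assembly GRCm38 through the accession without its version, which named 27656 of the 55681 probes and 20175 of those tested. No coordinate of that table was used. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. A call at an adjusted p under 0.25 follows the threshold the study states, and 0.05 is set beside it.

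Gene lists were tested with camera at a preset correlation of 0.01 on 1 probe per gene, the probe with the highest mean (15540 genes), with 0.05 as the threshold over 35 lists. A list of the KDM3 family had fewer than 5 measured genes and was not tested. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes.

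The groups, the tests, 36 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Jmjd1c and the KDM3 family. It also took the 12 largest rises and 12 largest falls among genes with a proper symbol, an adjusted p under 0.25 and the same direction in all 3 experiments, or all that passed where fewer did, which gave 12 rises and 7 falls. In each list described it took up to 4 genes with the smallest p.

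The labels number the experiments 1 to 3 in both groups. The deviations of same-numbered arrays from their group means correlated at 0.158, 0.597 and 0.726 across probes. All were over 0.1, so the numbers were taken to pair the samples. The pairing of experiment 1 is the weakest, since Jmjd1c hairpin replicate 2 correlated with control replicate 1 at 0.334, above the 0.158 of that experiment's own arrays. The main fit, fixed beforehand, left the pairing out, and each SE below comes from it. The fit with the experiment number as a block is given beside it. The choice mattered, since at 0.25 the main fit called 126 probes and the fit with the block called 642. The arrays lay on 2 slides. Slide 1 held both arrays of experiment 1 and slide 2 the other 4. With the slide as a block Jmjd1c was at -1.60 (adjusted p = 0.182). Within slide 1 its difference was -1.56, with no test, and within slide 2 it was -1.62. The highest correlation between 2 arrays was 0.993, and no arrays held identical values.

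The procedure was tested on data simulated for this comparison over 36317 probes, with 200 changed. At 0.25 it recovered 30 of 100 probes changed by 1 on the log2 scale and 90 of 100 changed by 2, with 37 false calls among 157. With the replicate block it recovered 4 and 82 of 100 at 0.25. At 0.05 the block recovered 0 of 100 at either size. The simulated noise held no effect of experiment, so these recoveries do not show how the block does on paired arrays. The list test called the 1 list that had been moved. The simulated genes varied independently, so this does not test the preset correlation where genes of a list move together. In the real data the estimated correlation of the ribosome biogenesis list was 0.40. The alternatives were the replicate and slide blocks, quantile and cyclic loess normalization, normexp background correction, the deposited table, other filters on dim or marked spots, 1 probe per gene, a trended robust variance, array weights, and leaving out arrays. Normexp was planned on the mean signal and was run on the median signal, since the scanner files used here hold no mean signal column.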

Results

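Gene expression was measured in mouse acute myeloid leukaemia cells, that is, bone marrow cells transformed by the MLL-AF9 fusion oncogene. The cells had received either a short hairpin RNA (shRNA) against Jmjd1c or a control hairpin, and were sorted 48 hours after retroviral infection. Jmjd1c encodes a JmjC-domain protein of the KDM3 family of histone demethylases. Each group held 3 arrays, 1 from each of experiments 1, 2 and 3. The labels name a single Jmjd1c hairpin, so effects of that hairpin on other transcripts cannot be told apart from effects of Jmjd1c loss. The labels do not say whether the 3 experiments used separate cultures or animals, so the p-values measure the spread between these samples, which may be technical. Between 54.4% and 68.7% of the spots on an array were well above background. The number of arrays limits the precision of every value below.

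The knockdown itself was examined first. The Jmjd1c probe was lower with the Jmjd1c hairpin in each of the 3 experiments, by a log2 fold change of -1.56 in experiment 1, -2.02 in experiment 2 and -1.22 in experiment 3. Its normalized log2 signal was 2.22 ± 0.46 (SD, n = 3) with the Jmjd1c hairpin and 3.83 ± 0.28 (SD, n = 3) with the control hairpin, a 3.03-fold difference. The limma estimate was a log2 fold change of -1.60 ± 0.28 (SE), with an adjusted p of 0.234, past the study's own threshold of 0.25 and not past 0.05. Leaving out any single array ended this call, although the estimate stayed between -1.78 and -1.34. With the experiment number as a block the limma adjusted p of Jmjd1c was 0.120. The related genes Kdm3a (log2 fold change -0.07 ± 0.35, SE), Kdm3b (0.04 ± 0.23, SE) and Hr (-0.01 ± 0.24, SE) did not pass the test.

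**Figure D1:**
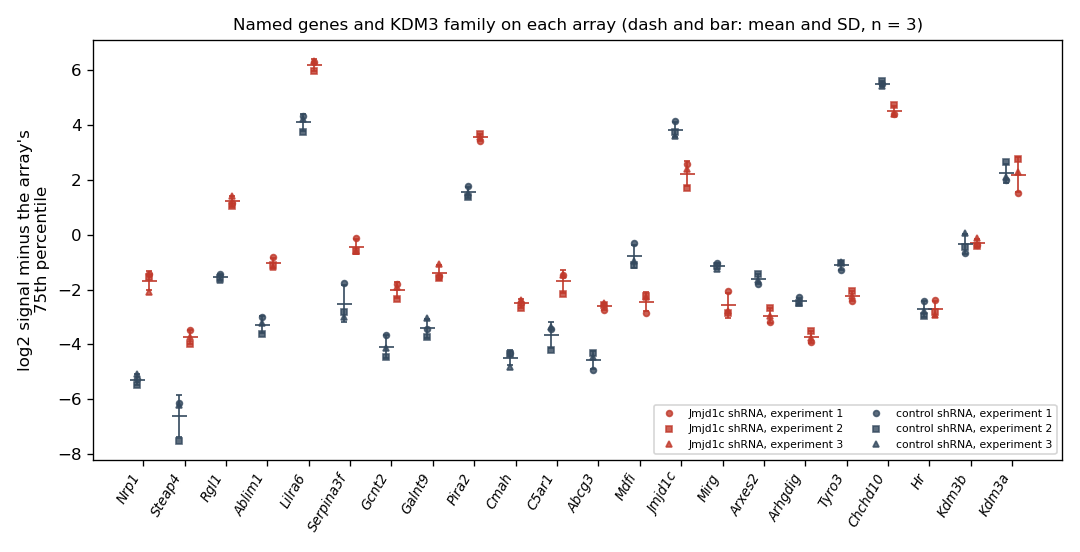
Normalized log2 signal (y axis, log2 signal minus the array's 75th percentile) of the named genes and of the KDM3 family on each of the 6 arrays. Points are single arrays, shaped by experiment, and the dash and bar give the mean and SD of 3 arrays. Jmjd1c averaged 2.22 with its hairpin and 3.83 with the control hairpin, while Hr, Kdm3b and Kdm3a overlapped between the groups.

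The comparison of the 2 groups asked which transcripts differ after Jmjd1c depletion. Among the largest rises, Nrp1, a co-receptor for semaphorins and VEGF, was not well above background on any control array and was at least 8.25-fold higher with the Jmjd1c hairpin (limma adjusted p = 0.0276). Steap4, a metalloreductase, was likewise not well above background in the controls and was at least 1.98-fold higher (limma adjusted p = 0.106). Rgl1, an effector of Ras-family GTPases, rose by a log2 fold change of 2.76 ± 0.19 (SE), 6.80-fold, with a limma adjusted p of 0.0276, and both of its probes passed. The actin-binding gene Ablim1 rose 4.75-fold and C5ar1, the receptor for complement C5a, rose 3.92-fold. Lilra6 rose 4.27-fold and Pira2 rose 4.01-fold. Both belong to a family of paired immunoglobulin-like receptors whose members are nearly identical in sequence, so which member each probe measured is uncertain. The others with large rises were Serpina3f (4.25-fold), the glycosyltransferase genes Gcnt2 (4.17-fold, well above background on 2 of 3 control arrays) and Galnt9 (4.05-fold), Cmah (3.93-fold, well above background on 1 of 3 control arrays) and the transporter gene Abcg3 (3.90-fold, on 2 of 3). The second Cmah probe gave a larger log2 fold change, 3.61 against 1.97. These sizes depended on the processing, and the bounds hold for the main values only. On the log2 scale the bound was 3.04 for Nrp1 and 0.99 for Steap4. Nrp1 lay below its bound after normexp and on the deposited table, and Steap4 lay below its bound after normexp. After normexp, which was run on another signal column and with an added offset, so that no single choice is isolated, the log2 fold changes of Steap4 (0.58), Gcnt2 (0.89), Galnt9 (1.05), Cmah (0.82), C5ar1 (1.06) and Abcg3 (0.72) no longer passed, with an adjusted p of 0.535 or more, while Nrp1 (1.44), Ablim1 (1.39) and Serpina3f (1.34) passed with smaller sizes. On the authors' deposited table the 11 of these 12 genes that it holds passed, but the log2 fold changes of Nrp1 (1.45), Ablim1 (1.41), Serpina3f (1.37), Gcnt2 (0.90), Galnt9 (1.05), Cmah (0.86), C5ar1 (1.10) and Abcg3 (0.72) were smaller there too. With no filter on dim probes 10 of the 12, all but Nrp1 and Rgl1, did not pass, and Serpina3f did not with cyclic loess (adjusted p = 0.256).

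Fewer genes fell. Besides Jmjd1c and 1 gene without a proper symbol, which the naming rule leaves out, the genes whose fall passed were Mdfi (log2 fold change -1.66 ± 0.28, SE), an inhibitor of myogenic transcription factors, the noncoding RNA Mirg (-1.44 ± 0.26, SE), Arxes2 (-1.33 ± 0.21, SE), Arhgdig (-1.30 ± 0.19, SE), the receptor tyrosine kinase gene Tyro3 (-1.12 ± 0.19, SE) and the mitochondrial gene Chchd10 (-1.01 ± 0.18, SE). The adjusted p of these 6 genes lay between 0.135 and 0.246. The second Tyro3 probe did not fall (log2 fold change 0.07). None of these 6 genes passed after normexp (adjusted p between 0.320 and 0.989) or with no filter on dim probes. After normexp Arhgdig was at -0.62, Tyro3 at -0.83, Arxes2 at -0.84, Mirg at -0.93, Mdfi at -1.25 and Chchd10 at -1.01. Mdfi, Arxes2, Arhgdig and Tyro3 did not pass with quantile normalization, Mdfi and Arhgdig with cyclic loess, or Mdfi and Chchd10 with the slide as a block. On the deposited table Arhgdig did not pass, and all 6 falls were smaller there, with Mirg at -0.95 and Arxes2 at -0.86. With the experiment number as a block all 6 passed 0.25, with a limma adjusted p between 0.0899 and 0.228.

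Over all 36323 probes tested, limma called 126 at an adjusted p under 0.25, with 113 higher and 13 lower in the Jmjd1c hairpin cells, and 3 at an adjusted p under 0.05, 1 probe of Nrp1 and 2 of Rgl1. With the experiment number as a block, 642 probes passed 0.25, 487 higher and 155 lower, and 0 passed 0.05, with 3783 at an unadjusted p under 0.05. On the authors' deposited normalized values the split was 283 higher and 100 lower, and after normexp background correction with quantile normalization it was 289 higher and 112 lower. With the replicate block added to these 2, more probes were lower than higher at 0.25, 2230 higher and 2549 lower on the deposited values and 2177 higher and 2457 lower after normexp and quantile normalization, while at 0.05 more were higher, 509 and 205, and 476 and 182. Leaving out any single array left between 0 and 61 probes past 0.25, and leaving out any 1 experiment left 0. With 1 probe per gene and the adjustment over all probes, 60 genes were called, 52 higher and 8 lower, and 371 with the replicate block, 277 higher and 94 lower. With the adjustment over those genes alone, 210 were called, 170 higher and 40 lower.

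Genes of growth and biosynthesis were lower as groups. All 49 measured ribosome biogenesis genes had a negative log2 fold change, with a median of -0.49, and camera gave an adjusted p of 1.4e-19. With an estimated correlation between genes the call was lost (adjusted p = 0.317). None of the 49 passed 0.25 over all probes, 2 passed as lower with the replicate block, and 41 passed adjusted over the list alone. Gnl3, a nucleolar GTPase, had a log2 fold change of -0.79 ± 0.19 (SE) and Rrp1b one of -0.71 ± 0.20 (SE), with an adjusted p of 0.630, and 0.248 with the replicate block. Of the 50 measured genes of the list of Myc and its targets, 47 were lower, with a median of -0.49 (camera adjusted p = 1.5e-16, and adjusted p = 0.324 with an estimated correlation). In that list 40 genes passed as lower adjusted over the list alone, 0 over all probes and 3 with the replicate block. Nolc1 had a log2 fold change of -0.86 ± 0.19 (SE), with an adjusted p of 0.383 and 0.198 with the replicate block. The list of DNA replication genes was also lower, in 43 of 45 genes, with a median of -0.40 (camera adjusted p = 2.2e-10, and adjusted p = 0.402 with an estimated correlation). The median was -0.64 in experiment 1, -0.23 in experiment 2 and -0.36 in experiment 3, and the level of the list on Jmjd1c hairpin replicate 2 (0.126) was above that on control replicate 3 (0.0044). Without experiment 1 the median was -0.30 (camera adjusted p = 1.9e-06). Mcm7, a subunit of the replicative helicase, had a log2 fold change of -0.62 ± 0.22 (SE), with an adjusted p of 0.796, and 0.320 with the replicate block. In the DNA replication list 0 genes passed over all probes, with or without the block, and 24 passed as lower adjusted over the list alone.

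Other lists lower by camera covered metabolism, stress and chromatin. In 7 of the 11 lower lists, those of DNA replication, oxidative phosphorylation, ATF4 targets, polycomb and trithorax, endoplasmic reticulum chaperones, H3K9 methyltransferases and mitosis, the level on Jmjd1c hairpin replicate 2 was above that on control replicate 3, so the groups overlapped. Of 60 oxidative phosphorylation genes 59 were lower, with a median of -0.18, of -0.12 after cyclic loess and of -0.30 without control replicate 3 (camera adjusted p = 1.3e-07, and adjusted p = 0.402 with an estimated correlation). The ATF4 target list had a median of -0.34 (camera adjusted p = 1.3e-05, and adjusted p = 0.402 with an estimated correlation), although Atf3 in that list was at 0.82 ± 0.22 (SE). In it 0 genes passed over all probes, and 1 as lower with the replicate block. The heat shock protein list had a median of -0.33, and of -0.21 without experiment 1 (camera adjusted p = 4.1e-05, and adjusted p = 0.331 with an estimated correlation). The polycomb and trithorax list had a median of -0.24, and of -0.38 without Jmjd1c hairpin replicate 2 (camera adjusted p = 0.000121, and adjusted p = 0.535 with an estimated correlation), and in it Suz12 was at -0.90 ± 0.23 (SE), with an adjusted p of 0.514, and 0.214 with the replicate block. Chaperones of the endoplasmic reticulum (median -0.16, camera adjusted p = 0.0317, and adjusted p = 0.622 with an estimated correlation) and H3K9 methyltransferases and heterochromatin proteins (median -0.23, camera adjusted p = 0.0492, and adjusted p = 0.434 with an estimated correlation) were near the threshold, and without experiment 1 neither passed (camera adjusted p = 0.157 and 0.104). With single arrays left out, the median lay between -0.26 and -0.045 for the first and between -0.38 and -0.065 for the second, and each lost its call in 4 of 6 cases. Neither passed with quantile normalization, with cyclic loess, after normexp or on the deposited table. With the slide as a block the second of these had a camera adjusted p of 0.0525, and 1 of its genes passed as lower over all probes with the replicate block against 0 without it. The mitosis list had a median of -0.14 (camera adjusted p = 0.0332, and adjusted p = 0.820 with an estimated correlation). It did not pass with quantile normalization, with cyclic loess, on the deposited table or without experiment 1 (median -0.0094, camera adjusted p = 0.987), and with single arrays left out its median lay between -0.35 and -0.027.

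Myeloid lineage genes moved in both directions. The monocyte and macrophage list was higher, in 29 of 35 genes, with a median of 0.45 (camera adjusted p = 1.2e-08, and adjusted p = 0.269 with an estimated correlation). None of its genes passed over all probes, 9 passed as higher with the replicate block, and 14 adjusted over the list alone, or 23 with the block. Ctss, a lysosomal protease, had a log2 fold change of 1.23 ± 0.23 (SE), with an adjusted p of 0.276, and 0.106 with the replicate block. Irf8, a transcription factor of monocyte development, had one of 0.83 ± 0.17 (SE), with an adjusted p of 0.312, and 0.188 with the replicate block. The list of primary granule genes, which mark granulocyte precursors, was lower with a median of -0.25 (camera adjusted p = 0.00165, and adjusted p = 0.331 with an estimated correlation). Mpo, which encodes myeloperoxidase, had a log2 fold change of -2.75 ± 0.59 (SE), with an adjusted p of 0.344, and 0.0779 with the replicate block, where 2 genes of the list passed as lower against 0 without it. The neutrophil maturation list was higher (median 0.17, camera adjusted p = 0.01, and adjusted p = 0.552 with an estimated correlation). Its level on Jmjd1c hairpin replicates 1 (-0.074) and 2 (-0.13) was below that on control replicate 3 (0.32), so the groups overlapped. Its median was 0.088 without experiment 1, 0.096 after normexp and 0.57 with array weights. With single arrays left out it lay between -0.13 and 0.39, and the list lost its call in 3 of 6 cases. In it Anxa1 rose by 1.69 ± 0.22 (SE) on the log2 scale, with an adjusted p of 0.0952. In it 1 gene passed over all probes, and with the replicate block 4 passed as higher and 1 as lower.

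Immune signalling genes were higher as groups. The type I interferon list was higher in 32 of 38 genes, with a median of 0.37 (camera adjusted p = 2.9e-08, and adjusted p = 0.393 with an estimated correlation). None of its genes passed over all probes and 5 passed as higher with the replicate block. Ifit3 was at 1.27 ± 0.26 (SE), with an adjusted p of 0.321, and 0.116 with the replicate block. The type I interferon list, like the heat shock list, had been fixed as a stress list, to look for responses to handling or infection. Both groups were infected with a hairpin, so infection as such is shared. Whether the rise of the interferon list was a response to unequal infection or to this particular hairpin was not tested. In the NF-kB and inflammatory cytokine list 26 of 31 genes were higher, with a median of 0.29, and of 0.19 after normexp (camera adjusted p = 4.1e-05, and adjusted p = 0.269 with an estimated correlation). Csf2, which encodes the cytokine GM-CSF, rose by 1.38 ± 0.19 (SE) on the log2 scale, with an adjusted p of 0.108, but was dim, well above background on 2 of 3 arrays of each group, so its size is uncertain. In this list 1 gene passed over all probes, and 4 with the replicate block. The IL-3 and STAT5 target list had a median of 0.21, and of 0.13 after normexp (camera adjusted p = 0.000151, and adjusted p = 0.317 with an estimated correlation), and its member Bcl6 rose by 1.41 ± 0.19 (SE) on the log2 scale, with an adjusted p of 0.110 (well above background on 2 of 3 control arrays). In this list too 1 gene passed over all probes, and 4 with the replicate block. Socs1 (log2 fold change 0.92), Cish (0.75) and Csf2rb2 (0.72) were higher without passing in the main fit, and 21 of 30 genes were higher. The list does not part genes that STAT5 raises from those it lowers, so its rise does not measure STAT5 activity. The labels give the cells either a conditioned medium or IL-3 and do not say which sample had which, so a difference in medium between the arrays was not tested. The hypoxia target list had a median of 0.18 (camera adjusted p = 0.00849, and adjusted p = 0.615 with an estimated correlation), but its median in experiment 1 was -0.13, and it was 0.053 without experiment 3, -0.17 with array weights, and between -0.019 and 0.28 with single arrays left out. In it 0 genes passed over all probes, and 1 as higher with the replicate block. Its level on Jmjd1c hairpin replicate 1 (-0.089) was below that on control replicate 2 (0.16), so the groups overlapped.

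**Figure D2:**
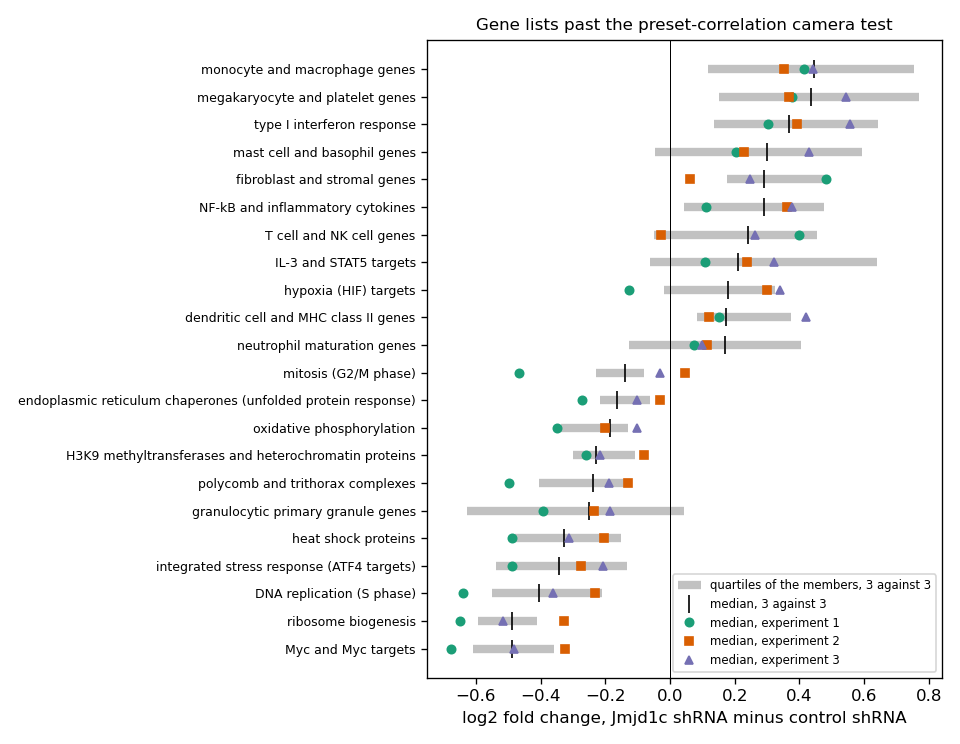
Log2 fold change (x axis, Jmjd1c hairpin minus control hairpin) of the 22 gene lists called by camera with the preset correlation. Grey bars span the quartiles of the members and black marks their median over 3 arrays against 3, and coloured symbols give the median in each experiment. The ribosome biogenesis median was -0.49 and the monocyte and macrophage median was 0.45.

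Lists of other cell types were tested as well. The megakaryocyte and platelet list was higher in 20 of 23 genes, with a median of 0.44, and of 0.21 after normexp (camera adjusted p = 1.2e-09, and adjusted p = 0.269 with an estimated correlation). In it Itgb3, an integrin of platelets, rose by 1.66 ± 0.19 (SE) and Pf4, a platelet chemokine, rose by 1.95 ± 0.28 (SE) on the log2 scale. In this list 3 genes passed over all probes, and 5 with the replicate block. Dendritic cell and MHC class II genes (median 0.17, camera adjusted p = 0.00540, and adjusted p = 0.317 with an estimated correlation), mast cell and basophil genes (median 0.30, camera adjusted p = 0.00684, and adjusted p = 0.317 with an estimated correlation), fibroblast genes (median 0.29, camera adjusted p = 0.00782, and adjusted p = 0.398 with an estimated correlation) and T and NK cell genes (median 0.24, camera adjusted p = 0.0346, and adjusted p = 0.402 with an estimated correlation) were also higher. With the replicate block 3 dendritic cell genes and 1 T and NK cell gene passed as higher over all probes against 0 without it, and 5 mast cell genes passed as higher and 1 as lower against 1 higher. After normexp the medians of these 4 lists were smaller, at 0.10, 0.12, 0.12 and 0.072, and the last 2 lists did not pass (camera adjusted p = 0.0591 and 0.0821). These 2 did not pass on the deposited table either (camera adjusted p = 0.275 and 0.136), and the T and NK cell list did not pass with quantile normalization (camera adjusted p = 0.155), with cyclic loess (camera adjusted p = 0.183) or with no filter on dim probes (median -0.0062). With single arrays left out the medians lay between 0.087 and 0.33 for dendritic cell genes, 0.15 and 0.37 for mast cell genes, 0.20 and 0.45 for fibroblast genes and 0.089 and 0.34 for T and NK cell genes. The groups overlapped in the dendritic cell, fibroblast and T and NK cell lists. In each, the level on Jmjd1c hairpin replicate 2 was below that on a control array. The fibroblast and the T and NK cell lists did not pass without experiment 1 (median 0.080 and 0.20, camera adjusted p = 0.105 and 0.0805). The B cell list (median -0.01, camera adjusted p = 0.973), the eosinophil list (median 0.22, camera adjusted p = 0.519) and the erythroid list (median -0.0045, camera adjusted p = 0.150) did not pass.

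The list of the MLL-AF9 and Hoxa/Meis1 programme, which includes Jmjd1c itself, did not pass, with 15 genes higher and 15 lower (median 0.0016, camera adjusted p = 0.235). In it 1 gene, Jmjd1c, passed as lower over all probes, and 3 with the replicate block, the others being Dot1l (log2 fold change -0.80, adjusted p = 0.199 with the block) and Cbx5 (-0.80, adjusted p = 0.213 with the block), whose second probe was at -0.33 and did not pass. The p53 target list (camera adjusted p = 0.973), the caspase and death receptor list (camera adjusted p = 0.347) and the BCL2 family list (camera adjusted p = 0.565) did not pass either. Of the 35 lists tested, camera called 22, of which 11 were higher and 11 lower. With an estimated correlation 0 were called, with 4 at an unadjusted p under 0.05, and fry called 0, with 12 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0609. No list call made with the preset correlation held with an estimated one.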

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

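The normexp settings on the median signal and the deposited table tested spot by spot were chosen after seeing the data. The Jmjd1c estimate kept its direction throughout. It was past 0.25 in the main setting. With quantile (-1.53) or cyclic loess normalization (-1.54), or with no filter on dim probes (-1.60), it was not. Leaving out arrays gave -1.79 to -1.34 with none past 0.25. The estimate was past 0.05 with array weights (limma adjusted p = 0.0195). So it was with the replicate block on the deposited table (limma adjusted p = 0.021) or after normexp and quantile normalization (limma adjusted p = 0.0243). No other setting brought it past 0.05. The count of 126 probes at 0.25 became 642 with the replicate block, 48 with normexp, 401 with normexp and quantile normalization, 4634 with these and the replicate block, 383 on the deposited table, 4779 on it with the replicate block, and, with each spot of it tested on its own, 451 spots of 413 probes, or 5771 spots with the block added. It was 3 without a filter on dim probes, 194 with probes above background on all 6 arrays, 210 with 1 probe per gene, 217 with a trended robust variance and 16780 with array weights, which gave control replicate 2 a weight of 9.06. The study states 451 transcripts at this threshold, the same number as the spots called without the block. Whether it counted spots or probes is not known here. The spot-by-spot test was 1 of several ways of testing that table tried after seeing the data. The count of 3 probes at 0.05 became 0 with the replicate block, the slide block, cyclic loess or no filter, 23 with quantile normalization, 16 with normexp, 31 with normexp and quantile normalization, 658 with these and the replicate block, 27 on the deposited table, 714 on it with the replicate block, 43 spots when tested spot by spot and 934 spots with the block added, 27 with probes above background on all 6 arrays, 28 with 1 probe per gene, 29 with a trended robust variance and 936 with array weights. Leaving out arrays gave 0 to 61 probes at 0.25, 0 at 0.05 and 16 to 21 lists. With both normexp and quantile normalization and the replicate block, 2177 probes were higher and 2457 lower. The 22 lists became 0 with an estimated correlation and 0 with fry, and 18 to 23 in the other settings with all arrays. The mitosis median was -0.0094 without experiment 1 (camera adjusted p = 0.987, the statistic of the other sign), and -0.35 to -0.0094 over the settings that leave out arrays. Of 24 settings, the call was lost in 13 for mitosis, 17 for the H3K9 methyltransferase list, 16 for endoplasmic reticulum chaperones, 16 for T and NK cell genes, 9 for fibroblast genes, 5 for hypoxia targets and 4 for neutrophil maturation. Array weights moved the medians of 12 called lists by more than 1.5 times. The replicate block brought the immediate early list past 0.05 (camera adjusted p = 0.0254) and changed no other list call. The cause of these differences was not tested, except that fewer arrays or tested probes change the adjustment by construction. Signal over background limits the dim probes, since Nrp1 and Steap4 have only bounds in the controls.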

Other observations

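The tests of cell makeup and of the first principal component were chosen after the lists' directions had been seen, and the features named in this part were chosen after their values were seen. Among the called probes without a gene name, 4 probes of a transcript that the array places on chromosome 14 from 77258025 to 77278750 (mm9, per the file headers) were higher. For 2 of them, not well above background on any control array, the signal was at least 5.04-fold and at least 2.83-fold higher. The other 2, above background on 2 and 1 of the 3 control arrays, had log2 fold changes of 1.72 and 1.59. A probe of an overlapping transcript from 77261377 to 77274982 was at least 2.25-fold higher. Pirb, of the same receptor family as Pira2, was at 1.60 ± 0.22 (SE, limma adjusted p = 0.122), with the same doubt about which member was measured. Hoxa9 (log2 fold change 0.07 and -0.05 for its 2 probes) and Meis1 (0.05), transcription factors of the MLL-AF9 programme, did not pass.

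The arrays differed among themselves in a way that neither the groups nor the slides follow. The first principal component held 51.0% of the variance and put Jmjd1c hairpin replicates 1 and 3 and control replicate 3 on one side and the other 3 arrays on the other. The split along it called 16779 probes at 0.25 and 2629 at 0.05, against 126 and 3 for the real groups, and 10550 and 10259 probes at 0.25 with quantile normalization and on the deposited table. Since this split was picked from the same arrays for how it parts them, a large count could follow from that choice. The count is not separate support for a structure beyond the component's share of the variance. The 3 arrays on the first side had 75th percentiles of 518, 341 and 300.3, the lowest of the 6. Both arrays of experiment 2, and both of experiment 3, lay on the same side, and those of experiment 1 on opposite sides. The labels name a choice of media without tying it to samples, so whether the structure follows the medium was not tested.

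The 6 arrays make only 10 splits, too few for a share under 0.05. At 0.25 and at 0.05, 2 of the 10 splits gave a count as large, the real one included. For lists it was 1 of 10, with 22 against a highest other of 19. Among the splits that take 1 array of each experiment, which part as many pairs as the real one, the highest other count was 0 probes at 0.25, 0 at 0.05 and 14 lists. The remaining splits put both arrays of some experiment together.

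More probes were higher than lower. If dim probes on a log scale were the whole cause, the brighter probes would be balanced. Of the 51 called probes brighter than the median probe, 94.1% were higher (exact 95% interval 83.8 to 98.8). After cyclic loess, which removes a shift that depends on brightness, 84.6% of 156 were higher (78.0 to 89.9). Both argue against these as the whole cause, but both intervals take probes as independent. Several called probes, such as those of Lilra6, Pira2 and Pirb, may measure the same transcripts, so the intervals may be too narrow. With normexp, quantile normalization and the replicate block the excess of higher probes was absent at 0.25 (2177 higher of 4634). It was present at 0.05 (476 higher of 658), so its size depends on the processing and the threshold. Its cause was not found.

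The ribosome biogenesis and Myc target lists were lower. Among the dimmest 7265 probes the median log2 fold change was 0.15, and among the brightest 7265 it was -0.051. Among 10000 random lists matched on signal, the ribosome biogenesis and Myc target medians lay at percentile 0 and 0. This argues against a shift with brightness as their whole cause. The endoplasmic reticulum chaperone and mitosis medians lay at percentile 3.77 and 6.91, so such a shift stays open for them. The other called lists lay at percentile 1.77 or lower, or at 98.45 or higher. In experiments 2 and 3 alone, the ribosome biogenesis and Myc target medians were -0.43 and -0.42, again at percentile 0 and 0. The arrays of each share a side of the first component but still differ along it. The Jmjd1c hairpin array was higher on it in experiments 2 (61.9 against 33.5) and 3 (-60.4 against -77.0). It was lower in experiment 1 (-23.0 against 65.1), while both lists were lower in all 3. This argues against that structure as the whole cause. The random lists take genes as independent, so the percentiles may overstate how unusual these lists are. An effect of Jmjd1c loss and an effect of this 1 hairpin on other transcripts both stay open, and no test here parts them.

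The monocyte and macrophage list was higher, at percentile 100 of matched random lists, which argues against a shift with brightness. A lower share of the main cell type was taken to raise other lineages alike. A gene would rise only as far as its signal comes from those other cells, so unequal medians alone cannot exclude a lower share. The 116 genes of the 8 lists of other cell types that were well above background on all arrays had a median of 0.18 (95% bootstrap interval 0.11 to 0.24). The monocyte median exceeded it by 0.25 (0.01 to 0.43), an interval that takes genes as independent. The medians ranged from 0.46 for megakaryocyte genes to 0.05 for erythroid, -0.01 for B cell and -0.09 for eosinophil genes. Whether all cell type lists moved alike was tested on the 145 genes, well above background on all arrays, that are in only 1 cell type list. In that set the erythroid median was 0.10 and the eosinophil median was 0.012. A permutation test of the Kruskal-Wallis statistic over genes gave p = 0.0613. A permutation test of the Friedman statistic over the experiments, with 10000 permutations, gave p = 0.0002. The second test took the same genes in each experiment. Its p shows that the order of the lists repeated, not that the lists differ beyond the genes chosen. Excluding the explanation was set to need both tests under 0.05, so it stays open. This is the third version of the test, and 2 earlier comparisons of medians would have excluded it by their first rules. Monocytes or macrophages among the sorted cells could also raise it. Of its 10 brightest genes 9 were higher, among them Lgals3 at 0.61 and Ctsb at 0.45, while Ly6c1 was at -0.06. Since 31 of its 35 genes were well above background on all control arrays, admixed cells and a change within the leukaemia cells cannot be told apart.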
